A study of Talpa occidentalis with 6 samples.

How the data were processed

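Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in gonads of wild-type Iberian moles (Talpa occidentalis) at postnatal day 7. There were 6 samples in 3 tissues with 2 samples each: the ovarian portion of the ovotestis, the testicular portion of the ovotestis, and the testis. Females of this species carry ovotestes, and males carry testes. Per the labels' protocols, gonads were dissociated into single cells, filtered, and tagmented with 50000 cells per reaction. Samples were assigned to tissues from the titles and source names in the labels.

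The values used were deposited by the authors as 1 genome segmentation per tissue. Each segmentation divides 4454 scaffolds of the assembly talOcc4 into segments carrying 1 of 5 numbered chromatin states, and the state number is a category without a scale. The labels attach the same segmentation to both samples of a tissue, so each tissue is 1 pooled value. No spread between samples, no test between samples and no value per sample could be computed. The sequencing depth of the samples is unknown. The method that assigned the states in the mole segmentations is not given in the sources used here, nor is whether the 3 tissues were segmented with 1 shared model. Comparisons between tissues assume that a state number means the same in each, and without that the overlaps, Jaccard indices and closed counts would compare unlike states. The submitters' processing notes name STAR 2.6.1d and the mouse build mm9, without saying which step or file they belong to. The library numbers in the titles place the samples of both ovotestis portions in 1 consecutive series and those of the testis in another. Any difference between the testis and a portion cannot be told apart from a difference between these library series, whereas the ovarian and testicular portions share a series.

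The segmentations cover 10493388 bins of 200 bp, or 2.10 Gb. The states form an ordered series: 99.6% to 99.8% of state boundaries, depending on the tissue, join states with neighbouring numbers. State 1, drawn in red in the deposited colour column, lies at 1 end of this series, and state 5, drawn in white, at the other. State 1 was taken as the accessible state. The design fixed before the data were examined called for the state most enriched at transcription starts. That enrichment was not computed, because the deposited gene annotation lies on another assembly (talOcc3) and shares 0 scaffold names with the segmentations. The choice of state 1 therefore rests on the colour and the order of the states alone, and states 1 and 2 together were run as the alternative. States 4 and 5 are called closed. The label thus takes in most of the genome, since state 4 alone covered 58.5% to 59.7% of it, depending on the tissue. Whether state 5 marks closed chromatin or absent signal was not tested.

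For each tissue, the number of state 1 segments, their summed length and their share of the segmented genome were computed. For each pair of tissues, a segment of one tissue was counted as shared if it overlapped a segment of the other by at least 1 bp, and the Jaccard index was the length accessible in both tissues divided by the length accessible in either. Shares carry Wilson 95% intervals, which cover counting error only. The Jaccard index carries a 95% interval from 1000 bootstrap draws of 5 Mb blocks, which covers variation along the genome and not between animals. The overlap by chance was taken from 100 random rotations of the segments along their own scaffold. The statistics were tested on simulated data: for a simulated pair of segmentations with 20000 segments, the placed share of common segments was recovered exactly at 3 of 3 levels. At these levels the segments had equal length and coincided fully or not at all. The recovery therefore checks the computation and not how the measures behave on these data. The counts of segments accessible in one tissue and closed in another, the patterns over 3 tissues, the 1 Mb windows and the shares per scaffold were chosen after seeing the data. Windows filled to at least 80% were kept. Positions are 1-based.

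The planned measures that join genes to accessibility were not run: the distribution over promoters, exons and introns, the number of open promoters, the accessibility of named loci and the accessibility of the gene lists. The rule for named genes, fixed before the data were examined, took the 10 genes with the largest locus ratio in each direction, members of fixed gene lists, and FGF9, CYP17A1, SOX9, AMH, DMRT1, FOXL2, WNT4, RSPO1 and FST wherever annotated. Its ratio part could not be applied, so named genes are described only by their position in the deposited annotation, whose start and end values are in bp on talOcc3. Neighbours that those genes called for were named after the annotation was read. The RefSeq gene table of the assembly MPIMG_talOcc4v2.1 was used for gene names and for which protein-coding genes neighbour each other. It held 13999 of the 18052 annotated symbols. Whether its positions hold on talOcc4 was checked after seeing the data, by sliding the gene ends of its 18 long gene runs along state 1 of the testicular portion, in windows of 10 Mb and by up to 2 Mb either way. At the best shift, gene ends met state 1 at a median of 10.5 times the mean over all shifts on the best scaffold, and at 5.36 times on the next. The best shift had a median over runs of 1.4 kb in the first window and 60.6 kb in the last, so the positions differ and were not carried over. The best shift was searched for on state 1 alone, so the check did not rank the states, and it was not used to choose the accessible one.

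The alternatives tried were states 1 and 2 together, segments of at least 400 bp, merging of segments less than 200 bp apart, an overlap of at least 50% of both segments or of the segment counted, and scaffolds of at least 1 Mb. After seeing the data, the results were also computed without 1 Mb windows that hold a state 1 segment of at least 5 kb, and on scaffolds 1 to 17 without scaffold 15. The 2 mouse segmentations of the series belong to no sample used here and were not used here. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.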

Results

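Accessible chromatin was mapped at postnatal day 7 in the ovarian portion of the mole ovotestis, in its testicular portion and in the male testis. The portions come from the same kind of female gonad, and the testis is the male counterpart of the testicular portion. Each tissue is represented by 1 segmentation that pools 2 samples, so differences between tissues have no replicate check. The depth is unknown, and the comparisons take each state to mean the same in all 3 tissues. All segment positions are on talOcc4.

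The 3 tissues held similar amounts of accessible sequence, and the testis divided it into more and shorter segments. This finer division was not particular to accessible sequence. Over all 5 states the testis had 893388 segments, against 795794 in the ovarian portion and 817931 in the testicular portion. State 1 covered 19.4 Mb in the ovarian portion, 19.2 Mb in the testicular portion and 18.9 Mb in the testis. These lengths were 0.923%, 0.914% and 0.901% of the segmented genome. The ovarian portion had 32268 accessible segments, the testicular portion 32701 and the testis 37137, or 1.15 times the number in the ovarian portion. The mean segment length was 600.4 bp in the ovarian portion, 586.6 bp in the testicular portion and 509 bp in the testis, and the median was 400 bp in each tissue. State 2, the next step of the series, covered a further 100.4 Mb in the ovarian portion, 93.2 Mb in the testicular portion and 98.5 Mb in the testis. The order of the testicular portion and the testis depended on the definition: with states 1 and 2 together the testicular portion had the smaller share, 5.36% against 5.6% in the testis.

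The accessible chromatin of the testicular portion lay closer to that of the male testis than to that of the ovarian portion of the same gonad type. The design sets these portions beside the testis to find which open chromatin the testicular portion shares with a male gonad. The Jaccard index was 0.56 for the testicular portion and the testis (95% interval 0.541 to 0.575). It was 0.534 for the ovarian and testicular portions (0.516 to 0.55) and 0.494 for the ovarian portion and the testis (0.483 to 0.506). The index of the testicular portion and the testis exceeded that of the portions by 0.0252 (0.018 to 0.0329). The index of the portions exceeded that of the ovarian portion and the testis by 0.0404 (0.023 to 0.055). Rotated segments gave mean indices of 0.00807 for the portions, 0.00782 for the testicular portion and the testis, and 0.00748 for the ovarian portion and the testis. The testicular portion and the testis were the closest pair on 16 of the 17 largest scaffolds. The exception was scaffold 2, where the ovarian portion and the testis had the highest index, 0.538, against 0.494 for the testicular portion and the testis. State 1 covered 1.52% of that scaffold in the testicular portion, 1.2% in the ovarian portion and 1.16% in the testis. Extra length in 1 tissue can lower its index, so this order need not mean that the ovarian portion matched the testis better. The testis belongs to another library series than the portions.

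**Figure D1:**
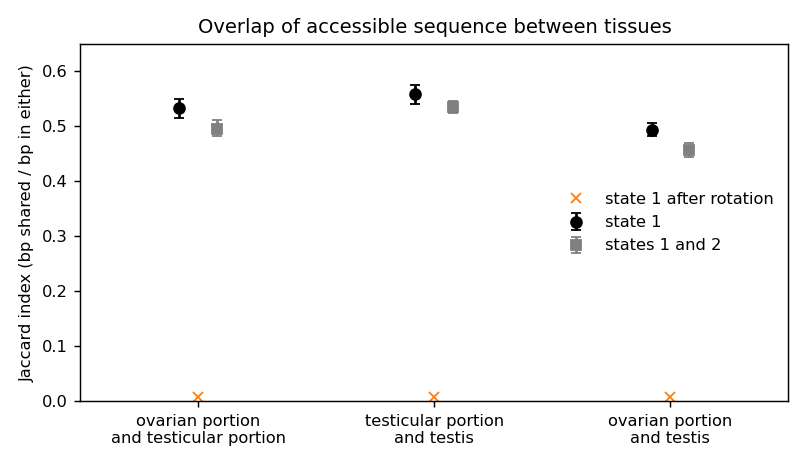
Jaccard index of accessible sequence (length in both tissues over length in either, no unit) for the 3 pairs of tissues. Circles are state 1, squares are states 1 and 2 together, bars are 95% intervals from 1000 draws of 5 Mb blocks, and crosses are the mean of 100 rotations; the testicular portion and the testis have the highest index under both definitions, 0.56 and 0.535.

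Between the ovarian and testicular portions, most accessible segments were shared, and the segments that were not shared were mainly 1 step lower in the other portion. Of the ovarian portion segments, 67.4% overlapped an accessible segment of the testicular portion (66.9% to 67.9%), and 66.4% of the testicular portion segments overlapped one of the ovarian portion (65.9% to 66.9%). A further 26.9% of the ovarian portion segments reached state 2 in the testicular portion, and 27.6% of the testicular portion segments reached state 2 in the ovarian portion. Segments accessible in the ovarian portion and closed in the testicular portion numbered 263, or 0.815% (0.723% to 0.919%). The reverse held for 87 segments of the testicular portion, or 0.266% (0.216% to 0.328%). With segments of at least 400 bp these counts were 87 and 19, and with states 1 and 2 together they were 7970 and 4788, so the ovarian portion had the larger count each time.

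Regions accessible in the ovarian portion and closed in both other tissues numbered 95, against 6 for the testicular portion. On the 17 largest scaffolds, the longest of the ovarian regions spanned 600 bp each, and the median over all regions was 200 bp for the ovarian as for the testicular portion. They lay on scaffold 10 at 59052201 to 59052800, on scaffold 15 at 36201 to 36800 and on scaffold 17 at 36740201 to 36740800. Regions of the testicular portion included one on scaffold 3 at 110133001 to 110133200 and one on scaffold 12 at 92732001 to 92732200. No gene was assigned to these regions, since the annotation used here lies on another assembly and the RefSeq table names a scaffold for 13 of its 21597 protein-coding genes.

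By states 1 to 3, the portions also differed over whole megabases. Genome-wide, most of this share was state 3, which neither definition calls accessible. It covered 30.9% of the segmented genome in the ovarian portion and 32.3% in the testicular portion. On scaffold 8, states 1 to 3 covered 19.4% of the window from 1000001 to 2000000 in the ovarian portion, 63.2% in the testicular portion and 41.1% in the testis. The next window, from 2000001 to 3000000, held 24.1%, 64.3% and 52.3%. On scaffold 10, the window from 94000001 to 95000000 held 8.34% in the ovarian portion, 46.9% in the testicular portion and 40.6% in the testis. In the opposite direction, the first 1 Mb of scaffold 15 held 70.8% in the ovarian portion, 39.5% in the testicular portion and 30.4% in the testis. The window from 100000001 to 101000000 of scaffold 13 held 80.6%, 56.7% and 48.0%. Among 2002 windows on the 17 largest scaffolds, states 1 to 3 were higher by at least 20 percentage points in the testicular portion in 66 windows and in the ovarian portion in 10. This excess depended on the margin and the states: at 10 percentage points the counts were 311 and 244. For states 1 and 2 together they were 3 and 5 at that margin and 0 and 0 at 20 points, and the median window was 0.54 percentage points higher in the ovarian portion. Scaffold 12 held 14 of those 66 windows.

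The testicular portion and the testis shared the most segments, and few segments of the testicular portion were closed in the testis. Of the testicular portion segments, 75% overlapped an accessible segment of the testis (74.5% to 75.5%), and 67.5% of the testis segments overlapped one of the testicular portion (67.1% to 68.0%). Only 32 segments of the testicular portion, 0.0979% (0.0693% to 0.138%), were closed in the testis. Segments of the testis closed in the testicular portion numbered 443, or 1.19% (1.09% to 1.31%). With segments of at least 400 bp these counts were 13 and 141, and with states 1 and 2 together they were 1988 and 8199.

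Regions accessible in both the testicular portion and the testis and closed in the ovarian portion numbered 25. The longest on the 17 largest scaffolds spanned 600 bp on scaffold 9 at 83746601 to 83747200. Another, of 400 bp, lay on scaffold 8 at 1318001 to 1318400, inside the window in which states 1 to 3 were lower in the ovarian portion. In comparison, 5 regions were accessible in both portions and closed in the testis, and 3 were accessible in the ovarian portion and the testis and closed in the testicular portion. States 1 to 3 were higher by at least 20 percentage points in the testicular portion in 8 windows and in the testis in 0, but by at least 10 points in 144 and 157. For states 1 and 2 together, 24 and 0 windows differed by 10 points, the largest difference being on scaffold 17 from 51000001 to 52000000, with 35% in the testicular portion and 17.4% in the testis. By states 1 to 3, the windows in which the testicular portion most exceeded the testis lay on scaffold 14. The window from 89000001 to 90000000 held 65.6% of states 1 to 3 in the testicular portion, 30.4% in the testis and 37.5% in the ovarian portion. The window from 83000001 to 84000000 held 58%, 30.5% and 27.2%. The testis most exceeded the testicular portion on scaffold 4 from 141000001 to 142000000, with 46.6% against 26.9%.

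The ovarian portion and the testis were the least alike of the 3 pairs by the Jaccard index. Of the ovarian portion segments, 67.8% overlapped an accessible segment of the testis (67.2% to 68.3%), and 60.1% of the testis segments overlapped one of the ovarian portion (59.6% to 60.6%). The ovarian portion thus shared 67.8% of its segments with the testis and 67.4% with the testicular portion, with overlapping intervals. The order of these shares depended on the setting: they were 66.3% and 63.9% with states 1 and 2 together, 68.9% and 70.6% with segments of at least 400 bp, and 63.8% and 64.4% with an overlap of at least 50% of the segment counted. Segments of the testis closed in the ovarian portion numbered 901, or 2.43% (2.27% to 2.59%), and segments of the ovarian portion closed in the testis numbered 243, or 0.753% (0.664% to 0.853%). With segments of at least 400 bp the counts were 354 and 71, and with states 1 and 2 together they were 10633 and 5803. Regions accessible in the testis and closed in both portions numbered 271, of which 13 lay on scaffold 18. The longest on the 17 largest scaffolds spanned 600 bp each, among them scaffold 3 at 45279001 to 45279600, scaffold 4 at 59049201 to 59049800 and scaffold 5 at 18344601 to 18345200. Because the testis alone comes from the second library series, these counts compare series as well as tissues.

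At the scale of windows, states 1 to 3 were higher by at least 20 percentage points in the ovarian portion in 66 windows and in the testis in 56. At 10 percentage points the order turned, with 295 windows higher in the ovarian portion and 392 in the testis. For states 1 and 2 together, 29 windows were higher by that margin in the ovarian portion and 0 in the testis. Scaffold 17 held 16 of the 66 windows at 20 points and scaffold 15 held 11. On scaffold 15, the window from 57000001 to 58000000 held 59.7% in the ovarian portion, 35.4% in the testicular portion and 19.1% in the testis. On scaffold 17, the window from 48000001 to 49000000 held 76.4%, 57.3% and 39.1%. In the opposite direction, the window from 93000001 to 94000000 of scaffold 12 held 9.36% in the ovarian portion, 44% in the testicular portion and 39.6% in the testis.

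Scaffold 15, of 88.9 Mb, stood apart from the other 16 large scaffolds in each tissue by its low share of states 1 to 3. They covered 23.9% of it in the ovarian portion, 13.5% in the testicular portion and 11.1% in the testis. The other 16 ranged from 31.9% to 53.4% in the ovarian portion, from 33.8% to 51.2% in the testicular portion and from 36.6% to 47.3% in the testis. State 5 covered 2.36% of scaffold 15 in the ovarian portion, 2.91% in the testicular portion and 4.56% in the testis. Each of these lay inside the range of the other 16, and scaffold 2 was higher in each tissue, with 5.31%, 5.51% and 4.86%. The pair closest to each other on scaffold 15 was again the testicular portion and the testis, with a Jaccard index of 0.604, against 0.538 for the portions and 0.455 for the ovarian portion and the testis.

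**Figure D2:**
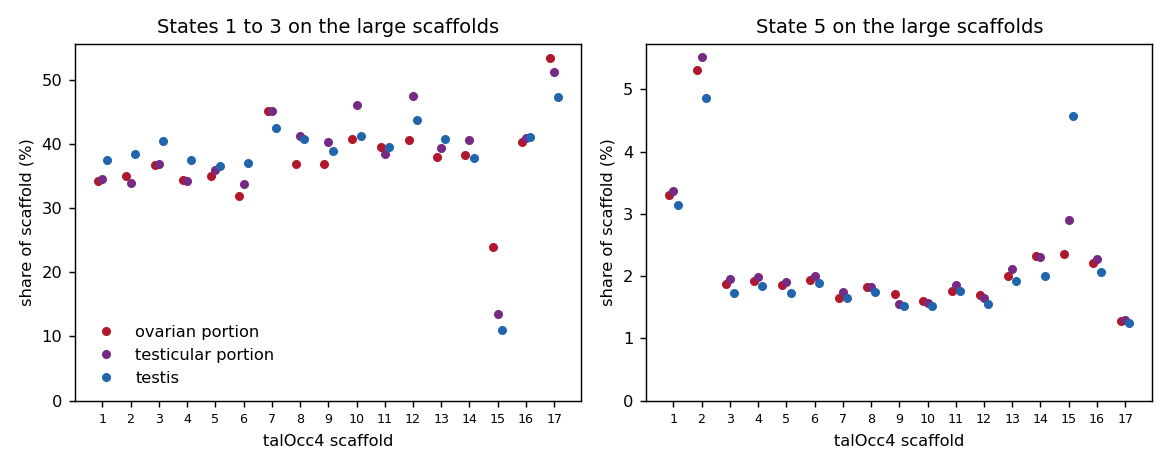
Share of each of the 17 largest talOcc4 scaffolds (percent of its length) in states 1 to 3 (left) and in state 5 (right), with 1 point per pooled tissue. Scaffold 15 has the lowest share of states 1 to 3 in each tissue, 23.9%, 13.5% and 11.1%, and a state 5 share of 4.56% in the testis against 2.36% in the ovarian portion.

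The gene annotation deposited by the authors gives the position of gonadal genes on the older assembly talOcc3. It held 23336 gene models with 18052 symbols, of which 2362 had more than 1 model and 724 had 3 or more. CYP17A1, the enzyme that turns progestogens into androgen precursors, had 3 models on scaffold 11, all on the minus strand. The model named CYP17A1_copy2 lay at 45100228 to 45105611, CYP17A1_copy3 at 45117841 to 45121591 and CYP17A1 at 45139044 to 45144553, and together they spanned 44.3 kb. The outer models had 8 exons and 1533 bp of exon sequence each, and the middle model had 6 exons and 1011 bp. WBP1L preceded them, and a TUBA1B model and BORCS7 followed. In the RefSeq table no gene carried the symbol CYP17A1, and genes without a name neighboured both WBP1L and BORCS7.

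FGF9, a growth factor that promotes testis development in the mouse, lay on scaffold 38 of talOcc3 at 11731991 to 11761319 on the minus strand, with 3 exons. Its annotated neighbours were MICU2, 132.3 kb away, and RUBCNL, 1.33 Mb away. The RefSeq table gave the same neighbours, RUBCNL and MICU2. The neighbours of SOX9 and RSPO1 were also the same in both sources, while AMH, DMRT1, WNT4 and FST differed between them on 1 side. Gene order was also compared across the annotation, using only genes with a single model in both sources. All other genes were set aside first, so paired genes may have others between them and need not be immediate neighbours. Of 12094 pairs adjacent in this reduced order, 11659 were also adjacent in the reduced order of the RefSeq table, or 96.4% (96.1% to 96.7%). Among pairs with a member of the fixed gene lists, 411 of 421 were.

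**Figure D3:**
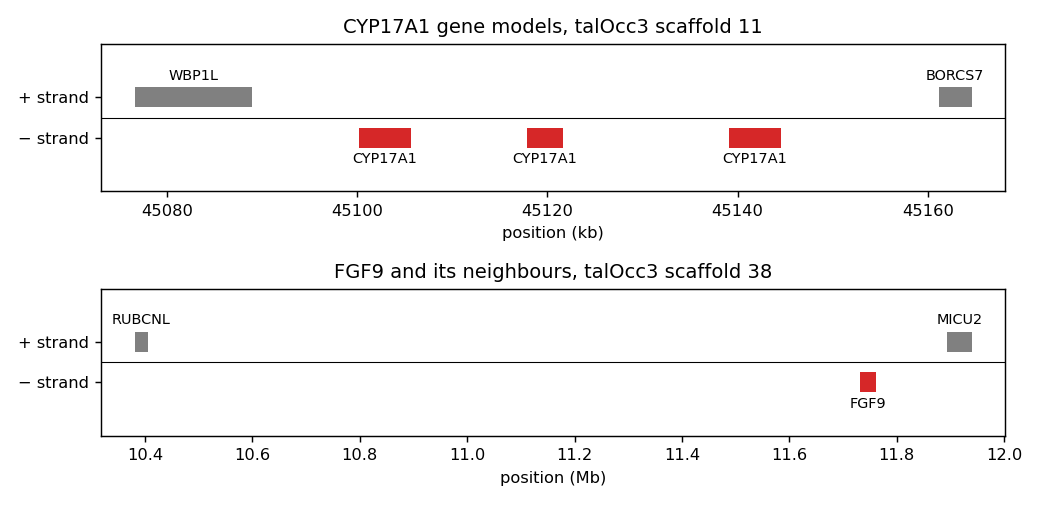
Gene models of CYP17A1 with WBP1L and BORCS7 on talOcc3 scaffold 11 (top, position in kb) and of FGF9 with RUBCNL and MICU2 on talOcc3 scaffold 38 (bottom, position in Mb), drawn to scale by strand; other models are not drawn. The 3 CYP17A1 models span 44.3 kb, and FGF9 lies 132.3 kb from MICU2 and 1.33 Mb from RUBCNL.

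The other genes named in advance had 1 model each where annotated. SOX9, which directs Sertoli cell differentiation, lay on scaffold 28 at 19363397 to 19364237 as a single exon of 841 bp between KCNJ2 and SLC39A11. Whether this model holds the whole gene was not checked. AMH, the hormone by which Sertoli cells regress the Müllerian ducts, lay on scaffold 14 at 6325712 to 6327173. DMRT1, a transcription factor that maintains testis identity, spanned scaffold 15 of talOcc3 from 19940607 to 20035259 with 7 exons. WNT4 and RSPO1, which act in ovarian differentiation, both lay on scaffold 2 of talOcc3, at 91031241 to 91040418 and at 80471444 to 80475377. FST, the activin-binding protein follistatin, lay on scaffold 8 of talOcc3 at 25729194 to 25732596. FOXL2, a transcription factor of granulosa cells, had no model in the annotation used here, and in the RefSeq table it neighboured PIK3CB.

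Of the 309 genes on the 14 fixed lists, 271 were annotated, and 33 of the 38 others had a symbol in the RefSeq table. The Sertoli cell list had 25 of 29 members annotated, without SOX8, PTGDS, DHH and CST9. The granulosa cell list had 22 of 25, the Leydig cell and steroid synthesis list 24 of 27, the oocyte list 21 of 24 and the meiosis list 23 of 24. The spermatogonia list had 17 of 24, without NANOS2, UTF1, ID4, PIWIL4, MAGEA4, DNMT3L and SOX3. The peritubular list had 14 of 15, the interstitial list 22 of 22, the endothelium list 14 of 18, the immune list 18 of 18 and the mesonephros list 12 of 13. The WNT target list had 17 of 18 and the housekeeping list 19 of 20. The homeobox list had 30 of 39, and 7 of the 9 missing genes were HOXB members.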

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

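Of the 117 values recomputed under an alternative that could change them, 48 stayed within the limits set and 69 moved. For shares and Jaccard indices the limit was the 95% Wilson interval of the main value, which covers counting error only and is narrower than the block bootstrap interval, and for counts it was 1.5 times. The testicular portion and the testis had the highest Jaccard index, and the ovarian portion and the testis the lowest, under each alternative that changes the index. Merging segments less than 200 bp apart could change nothing, since gaps are whole bins of 200 bp, and is not counted. The measures that need genes on talOcc4 were not run, nor were their alternatives. Depth is unknown, and no value was recomputed at another depth. No replicate could be left out, because each tissue is 1 pooled segmentation. No paired analysis was possible because the segmentations carry no replicate numbers. Where no reason is given, the cause was not tested.

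With states 1 and 2 together, which adds sequence by construction, the accessible share was 5.71% in the ovarian portion, 5.36% in the testicular portion and 5.6% in the testis, in 108116, 108190 and 123324 segments. The Jaccard index was 0.496 for the portions, 0.535 for the testicular portion and the testis, and 0.456 for the ovarian portion and the testis. The shared segments were 63.9% of the ovarian portion with the testicular portion, 66.3% of it with the testis and 73.1% of the testicular portion with the testis. Ovarian portion segments closed in the testicular portion and in the testis numbered 7970 and 5803. Testicular portion segments closed in the ovarian portion and in the testis numbered 4788 and 1988, and testis segments closed in the ovarian and testicular portions numbered 10633 and 8199.

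With segments of at least 400 bp, which leaves fewer segments, the shares were 0.832%, 0.82% and 0.781% in the same order, and the testis kept 24623 segments. The indices were 0.546 for the portions, 0.566 for the testicular portion and the testis, and 0.505 for the ovarian portion and the testis. The shared segments, in the order above, were 70.6%, 68.9% and 75.5%. The closed counts, in the order above, were 87, 71, 19, 13, 354 and 141.

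The stricter overlaps lower the shared segments by construction: to 60.5%, 60.7% and 68.7% with at least 50% of both segments, and to 64.4%, 63.8% and 72.0% with at least 50% of the segment counted. On scaffolds of at least 1 Mb, 75.7% of the testicular portion segments were shared with the testis.

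The last 2 alternatives were chosen after seeing the data. Without windows that hold a state 1 segment of at least 5 kb, the shares were 0.883% in the ovarian portion, 0.831% in the testicular portion and 0.865% in the testis, so the testicular portion had the smallest share. The indices were 0.543 for the portions, 0.571 for the testicular portion and the testis, and 0.488 for the ovarian portion and the testis. Shared segments were 66.7% of the ovarian portion with the testicular portion and 77.5% of the testicular portion with the testis. On scaffolds 1 to 17 without scaffold 15 the accessible shares were 0.938%, 0.905% and 0.923%, again lowest in the testicular portion. There the index was 0.543 for the portions and 0.567 for the testicular portion and the testis, and 77.0% of the testicular portion segments were shared with the testis.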

Other observations

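All tests in this part were chosen after the patterns had been seen. Outside the large scaffolds, 1304 scaffolds, 17 Mb in sum, were wholly in state 5 in each tissue. The longest of them was scaffold 21. On scaffold 19, of 3.78 Mb, state 1 covered 6.45% in the ovarian portion, 8.54% in the testicular portion and 4.97% in the testis. Scaffold 20 held 3.81%, 10.6% and 3.43%. On scaffold 18, of 18.4 Mb, state 1 covered 0.262% in the ovarian portion, 2.12% in the testicular portion and 0.509% in the testis. The Jaccard index there was 0.0364 for the portions, 0.186 for the testicular portion and the testis, and 0.125 for the ovarian portion and the testis. Such unequal amounts limit the index, which cannot exceed the smaller length divided by the larger. On scaffolds 19 and 20 the ovarian portion and the testis were the closest pair, with 0.702 and 0.582, against 0.564 and 0.325 for the testicular portion and the testis. State 1 covered more of both scaffolds in the testicular portion, which limits its indices there. These indices alone therefore do not show that its sites differ from those of the testis.

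Scaffold 15 held less of states 1 to 3 in the testis and the testicular portion than in the ovarian portion. The ratios were 0.464 for the testis and 0.564 for the testicular portion. For states 1 and 2 together, the testis ratio was 0.678, against a lowest of 0.702 over the other 16 large scaffolds. The testicular portion ratio was 0.686, against a lowest of 0.807. Between the testis and the testicular portion it was 0.988, inside the range of the other 16, 0.869 to 1.22. Under 1 shared model, shallower libraries would lower the other large scaffolds too. Over those 16 the median ratio for states 1 to 3 was 1.06 for the testis and 1.02 for the testicular portion. Under that model this argues against shallower libraries as the whole cause. With a model fitted to each tissue, shares could stay level at any depth, so the medians could not decide. A first bound for the testis, that each of the 16 stay at 0.9 or above, was missed by scaffold 17 (0.884). For the testis, a candidate explanation is that scaffold 15 belongs to a chromosome with 1 copy in males: state 5 took 1.93 times the share it had in the ovarian portion, against a median of 0.954 times over the other 16. State 5 was also raised in the testicular portion, a female tissue, to 1.23 times the ovarian portion (0.905 to 1.05 on the other 16), and the testis to testicular portion ratio was 1.57 for state 5 but 0.822 for states 1 to 3, so most of the drop in states 1 to 3 lay between the female portions and is left open, as are a difference between the tissues and the library series of the testis.

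On scaffold 18, 2.88 Mb were in state 5 in both portions and out of it in the testis, against 0.32 Mb the other way round, a ratio of 9.01. Under 1 shared model, deeper testis libraries would raise this ratio elsewhere. Its median over the 16 large scaffolds was 0.736 and its highest value there 1.15, though the small scaffolds 19 and 20 had 3.34 and 2.12. Sequence present only in males may account for the pattern, as a hypothesis. The ratio of 9.01 meets the bound set for it. It restates the pattern, and the bound was set afterwards, so it gives the hypothesis no support of its own. Elsewhere, 1 of 1345 scaffolds of 20 to 500 kb was out of state 5 in the testis only over at least 50% of its length. That count cannot decide, because scaffolds wholly in state 5 in each tissue can never pass. Nor need the sequence on scaffold 18 recur on others. The sequence lay at 1 end of the scaffold: 73.7% of the first 1 Mb, 72.3% of the window from 1000001 and 70.1% of that from 2000001 were out of state 5 in the testis only, and 3.66% of the window from 4000001. The library series of the testis stays open too, and no gene was assigned to the scaffold.

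In 12 of 2024 windows of 1 Mb, 6 of them on scaffold 2 between 30000001 and 42000000, state 1 took at least 5 percentage points more in the testicular portion than in both other tissues. Under 1 shared model, deeper testicular portion libraries would raise the other windows too, but there the median difference from the ovarian portion was -0.06 percentage points. Reads piled on repeated sequence could give such windows: the mean state 1 segment there was 1.46 times as long as elsewhere (95% interval 1.28 to 1.68), which does not clear the bound of 1.5 set for or against it; the interval was added after the ratio, below that bound, had been seen. The ratio was 1.28 in the ovarian portion and 1.42 in the testis, and the median was 400 bp inside and outside these windows in each tissue. Long segments were nevertheless concentrated there. In the testicular portion, segments of at least 5 kb held 19.7% of state 1 in these windows and 1.05% elsewhere. The shares were 17.6% and 0.4% in the ovarian portion, and 14.6% and 0.287% in the testis. The concentration was thus present in each tissue, and no bound was set for it. These windows were chosen for their state 1 in the testicular portion, so longer segments in that portion may follow from the choice. State 1 took 0.26% to 15.3% of these windows in the ovarian portion and 0.4% to 13.8% in the testis. The shares over the segmented genome were 0.923% and 0.901%. Over the genome, state 1 segments of at least 5 kb numbered 55 (564 kb) in the testicular portion, 24 (256.2 kb) in the ovarian portion and 19 (206 kb) in the testis, so repeated sequence stays open and cannot be told apart from a difference of the tissue.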
